A study of Homo sapiens with 6 samples.

How the data were processed

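The samples were total RNA of ES-2 cells, an established line derived from a human ovarian clear cell carcinoma. Per the labels' protocols, cells were transfected with a double-stranded mimic of the microRNA mir-22 at 65 nM or with a negative control mimic modelled on worm microRNAs, and were harvested 48 hours later. No dose is recorded here for the control mimic, so whether the groups received equal amounts of mimic is not known. A mimic raises the activity of the microRNA it copies. The 6 samples form 2 groups of 3 arrays each, as their labels name them. The labels call the samples of a group biological replicates without saying whether they came from separate days or cultures, so p-values measure the spread between these arrays.

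Each array was a 1-colour Illumina bead array. The authors summarised the bead intensities with BeadStudio, per the submitters' processing notes, whose version is not given in the sources used here. Per the file headers, the deposited array files hold for each probe the mean intensity of its beads, the spread of the bead intensities, the number of beads and a detection score. The deposited intensity values are on a linear scale. They were neither background-subtracted nor normalised between arrays, since their quantiles differ between arrays and the lowest value of any array lies between 26.8 and 31.1. The deposited detection score runs from 0 to 1 and rises with intensity, so a detection p was taken as 1 minus the score. The authors also deposited a value table of the same arrays, which names the probes. Its intensity values have the same median of 48.6 on every array, the mimic replicate 1 values are unchanged, and those of the other arrays are a rising function of their raw intensities. That points to a normalisation towards that array, and how it was done is not given in the sources used here.

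The array files carry numeric probe codes and the value table carries probe names, so rows were joined by their values over the 6 arrays. All 48803 rows matched 1 to 1 without a tie. Gene symbols came from the platform annotation supplied for the value table, and were compared through Entrez gene identifiers with the RefSeq gene table of GRCh38.p14, which changed none of them and also gave the RNA types. Of the probes, 28098 had 1 gene symbol, 13 had several and 20692 were unnamed here, and the named probes stood for 18853 genes. No genome coordinates are given because the build of the array annotation is not given in the sources used here.

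Intensities were processed in limma 3.58.1 under R 4.3.3 with the neqc function, which fits a normal-exponential background using moments of the negative controls inferred from the detection p, adds an offset of 16, applies quantile normalisation and takes log2. Low signals are compressed by the offset, so fold changes of dim probes are understated. A probe was kept if its detection p was under 0.01 on at least 3 of the 6 arrays, whichever these were, which left 18732 probes for 11133 genes, with 3830 of the kept probes lacking a single symbol. The arrays detected between 35.8% and 39.4% of all probes, and a probe's mean rested on a median of 41 to 42 beads. The median standard error over beads was 3.63% to 5.08% of a detected probe's intensity. The median standard error of a log2 fold change was 0.122. Standard errors of log2 fold changes, here and after ±, are limma's moderated ones, which borrow spread from all kept probes.

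Each kept probe was compared between groups with limma's linear model and empirical Bayes moderated test (no trend, not robust), mir-22 mimic minus control mimic, two-sided, with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. A gene's level is that of its brightest kept probe, and other probes of a gene in the report are given where any was opposite in sign or over 1.5 times apart in log2 fold change. Of these genes, H4C8, ADM, MDM2, RHOB and HDAC4 were above background on 2 of 3 control arrays, ERBB3 on 1 of 3, and TP53INP1 on 2 of 3 mimic arrays. A probe under the detection limit on every array of a group has only a bound there. That bound is the other group's mean against the mean, over arrays, of the higher of the lowest detected signal and the probe's own. Gene lists were tested with limma's camera function at a preset inter-gene correlation of 0.01 on 1 probe per gene, adjusted over the 36 lists. Camera compares a list with all other measured genes, and was rerun with an estimated correlation and beside fry, which asks only whether a list's genes move one way. Of 901 list entries 841 were on the array.

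The lists, the tests of genes and lists, the rule for naming genes and all alternatives but 1 were fixed before the data were examined, and tests chosen later are marked as such. Named were the 12 genes with the highest and the 12 with the lowest log2 fold change among those past the threshold whose groups did not overlap, up to 4 members with the lowest adjusted p of each list that passed or had a called member, genes chosen beforehand (among them MAX, HDAC4, SIRT1, CDK6, ESR1, MYCBP, ERBB3, TP53INP1 and MIR22HG), and genes that an alternative turned round. The text gives examples of the list members so named, and marks genes chosen after their values were seen.

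Both groups carry the numbers 1 to 3 in their labels. Whether these pair the arrays was checked through the correlation, across probes, of same-numbered arrays' deviations from their group means. It was 0.334 for number 1, 0.135 for number 2 and 0.434 for number 3, each over the cut of 0.1 used for pairing. Arrays of different number and group had values from -0.40 to 0.315. Mimic replicate 1 with control mimic replicate 2 (0.315) and mimic replicate 2 with control mimic replicate 1 (0.181) passed the cut too. The check therefore does not single out pairs 1 and 2, and pairing by number is an assumption resting on the labels. The comparison was run without the number as a block, and with it as an alternative.

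The alternatives were 2 other background corrections, median scaling or cyclic loess in place of quantile normalisation, no detection filter or detection on all 6 arrays, the authors' value table, the replicate number as a block, a trended and robust variance, array weights, a per-probe test without shared variance, the mean over a gene's probes, 2 other list tests, and leaving out each array in turn. Leaving out both number 3 arrays was added after control mimic replicate 3 had been seen to stand apart. A test of mir-22 seed matches in 3' untranslated regions was planned but needs transcript sequences, which were not used here, and slides were not tested as a batch because the files name none.

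The tests were checked on simulated data: arrays drawn for the 18732 kept probes with their own means and spreads, with 200 changed probes per run, over 20 runs of this comparison. The limma test recovered 13.4% of probes changed by a log2 of 0.5 and 72.4% of those changed by 1, and 4.5% of its calls were false. Camera passed 0.33% of lists without a shift and 100% of lists shifted by 0.3. Probes were drawn independently, without any pairing of arrays or correlation between genes, so these rates hold for such data and may be too favourable for the real arrays. In the other direction, 200 of 18732 is a smaller share than the 6.46% called in the real comparison. A smaller share makes the adjustment stricter, so which way the recovery rates err is not known. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.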

Results

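Gene expression was measured in ES-2 ovarian clear cell carcinoma cells 48 hours after transfection with a mir-22 mimic or with a control mimic, with 3 arrays per group. The series was set up to ask how transcript levels respond when mir-22, which the submitters describe as low in ovarian cancer, is raised. Between 17465 and 19244 of the 48803 probes were detected per array, the fewest on control mimic replicate 3 and the most on mir-22 mimic replicate 1. The upper quartile of raw intensity ran from 78.1 on control mimic replicate 3 to 96.2 on mir-22 mimic replicate 1. Mimic replicate 3 was next lowest at 80.0. The median standard error over beads was also highest on both number 3 arrays, at 5.08% (mimic) and 4.71% (control), against 3.63% to 3.99% on the others.

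The mimic arrays resembled one another, and control mimic replicate 3 stood apart. Across the 18732 kept probes, log2 values correlated at 0.995 to 0.998 between mimic arrays and at 0.997 between control mimic replicates 1 and 2, while control mimic replicate 3 correlated with these controls at 0.980 and 0.981. Principal component 1 held 60.1% of the variance and set that array against the other 5, and component 2 held 24.6% and set the mimic arrays (6.61 to 18.09) against control mimic replicates 1 and 2 (-21.13 and -20.56), with control mimic replicate 3 at 8.65, within the range of the mimic arrays. On control mimic replicate 3, 684 probes lay more than 1 log2 unit below the mean of the other controls and 5 lay as far above it. Of the mimic arrays, replicate 3 lay nearest to it on component 1 (-9.11, against -21.33 and -18.4). Control mimic replicates 1 and 2 lay nearer still (-1.36 and 0.11).

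**Figure D1:**
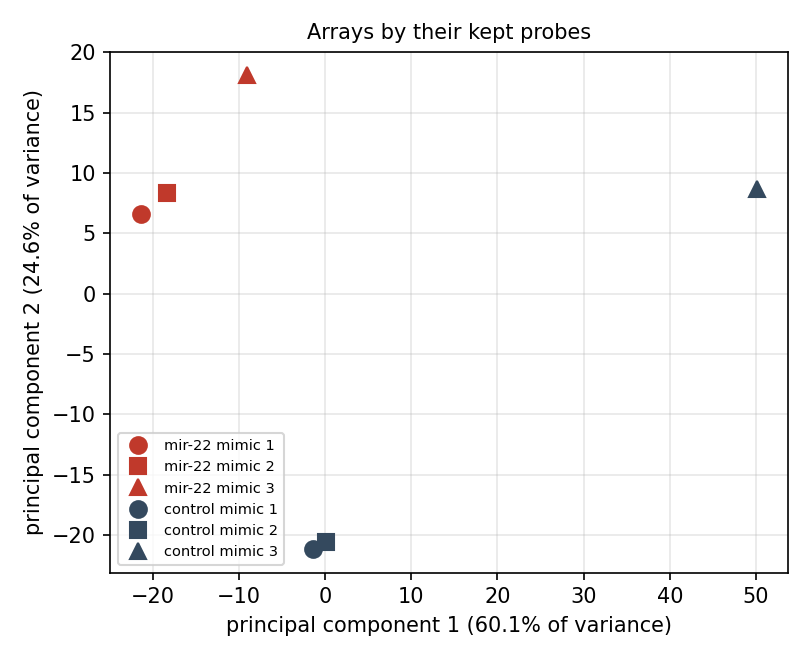
Arrays on the principal components 1 (60.1% of variance, x axis) and 2 (24.6%, y axis) of the kept probes' log2 values, in units of log2 intensity; each point is an array, red for mir-22 mimic and dark for control mimic, with a marker shape per replicate number. Control mimic replicate 3 lies at 50.09 on component 1, and the other arrays lie between -21.33 and 0.11.

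The largest rise with the mir-22 mimic was in IL1RL1, a receptor of the interleukin family. Its brightest probe was not above background on any control array and rose at least 5.71-fold, a log2 of 2.51 (adjusted p = 0.000145, limma). Its other probe, above background on 1 of 3 control arrays, was also called higher but by a smaller log2 of 1.04. THBS1, which encodes the matrix glycoprotein thrombospondin, rose by a log2 of 1.89 ± 0.12 (moderated SE, 3 arrays per group), or 3.71-fold. The other 10 of the 12 largest rises were in the glycosyltransferase GALNT1 (log2 1.84 ± 0.25), the annexin ANXA10 (1.74), the histone genes H4C14 (1.52) and H4C8 (1.43), the cytokines IL11 (1.47) and IL1B (1.41), the tyrosine kinase TXK (1.47), the cell cycle kinase CDK6 (1.39), the glutathione transferase GSTM3 (1.39) and the zinc finger gene BNC2 (1.34).

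The largest decreases were smaller than the largest rises. SFXN2, a mitochondrial carrier, had a log2 fold change of -1.36 ± 0.12, followed by the mRNA decapping factor EDC3 (-1.33), EEF2K, the kinase that slows translation elongation (-1.31), the dolichol-phosphate mannose synthase subunit DPM2 (-1.29), the tubulin-modifying enzyme TTLL5 (-1.28) and the mitochondrial lipid transfer protein PRELID1 (-1.26). The integrin gene ITGA10 (-1.25), TM4SF19 (-1.23), the Wnt pathway transcription factor LEF1 (-1.20), LYPLA2 (-1.16), the phosphodiesterase PDE7B (-1.13) and the chloride channel gene CLCC1 (-1.13) completed the 12. The other probe of LEF1 was at -1.18, whereas the other probe of CLCC1 was at 0.28. Adjusted p-values of these 24 genes lay between 0.000145 and 0.0131 (limma). The groups of arrays did not overlap for any of them, which the rule for naming genes required. Leaving out 1 array ended a call for 2 of the 24. GALNT1 lost its call without mimic replicate 1 (log2 1.79, adjusted p = 0.0541) or 2 (1.84, 0.0532), over a range of 1.79e-05 to 0.0886 in its alternatives. PDE7B lost its call without mimic replicate 1 (-1.11), 2 (-1.14) or 3 (-1.15). The per-probe test without shared variance did not call GALNT1, TXK, H4C8, IL1B, EDC3, TM4SF19 or PDE7B.

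**Figure D2:**
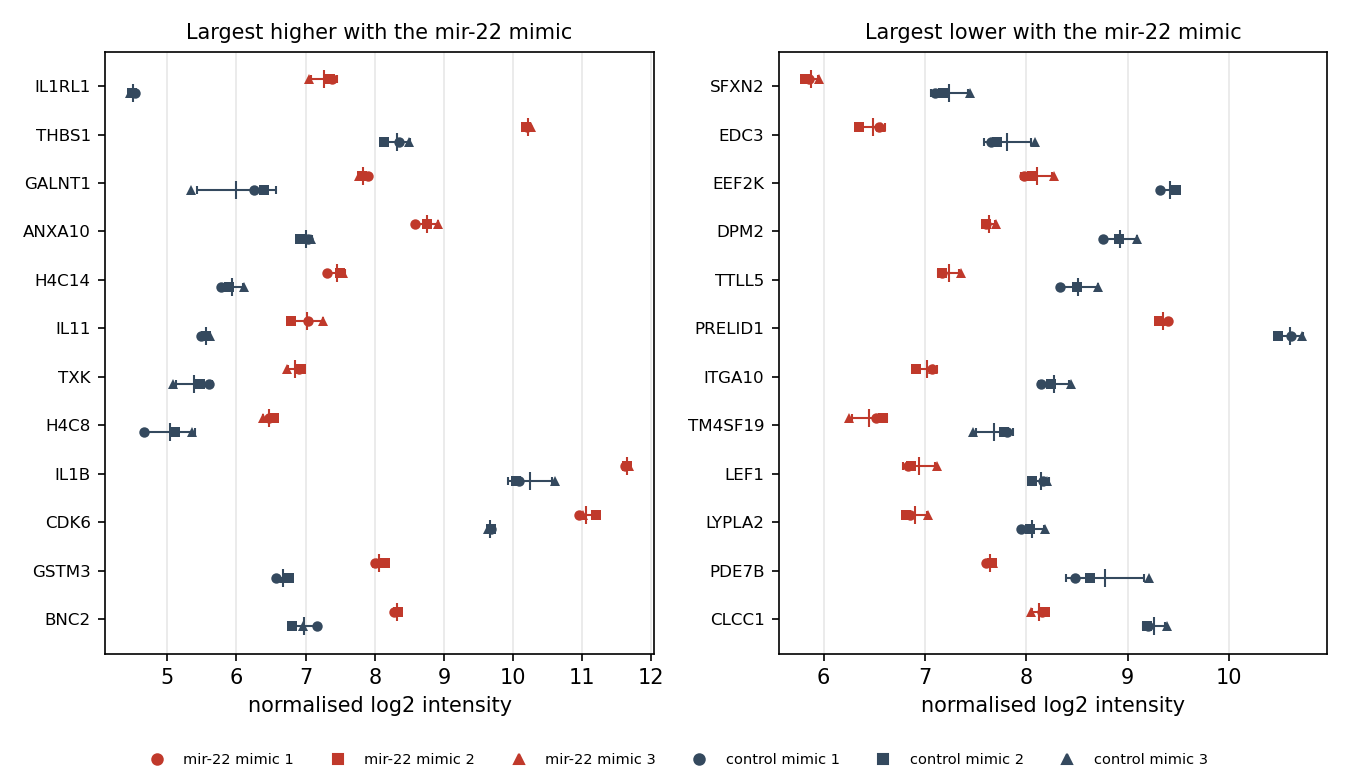
Normalised log2 intensity (x axis) of the 12 genes with the largest rises (left) and the 12 with the largest decreases (right) with the mir-22 mimic; points are arrays, red for mir-22 mimic and dark for control mimic, with a marker shape per replicate, and vertical ticks with bars give the mean and SD of 3 arrays. As the rule for naming genes required, the 2 groups of arrays are apart for each gene, from IL1RL1 (means 7.26 and 4.50) to CLCC1 (8.13 and 9.26).

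In all, 1210 of the 18732 probes (6.46%) passed the threshold in limma, 569 higher and 641 lower with the mimic, standing for 964 genes, of which 455 were higher and 509 lower. At least a 1.5-fold change was seen in 647 of these probes, 305 higher and 342 lower. Groups of arrays did not overlap for 31.3% of the kept probes, where chance gives 10% if all 6 arrays are exchangeable, a value that takes no account of pairing by replicate number. Of 357 genes with several kept probes and at least 1 called, 73 had every probe called, none had probes called in opposite directions, and 53 had a probe of opposite sign. The counts depended on each array: without mimic replicate 1, 2 or 3 the test called 134, 133 or 209 probes, and without control mimic replicate 1, 2 or 3 it called 599, 421 or 2639. All 1210 probes called with 6 arrays were called again without control mimic replicate 3. All kept their sign whichever array was left out, which says little. Groups of arrays did not overlap for any of the 1210, so leaving out 1 array could hardly turn a sign. Of the 84 called genes that the naming rule picks, 27, 28 and 35 kept their call without mimic replicates 1, 2 and 3, and 58, 51 and 84 without control mimic replicates 1, 2 and 3; 26 kept it in every case.

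**Figure D3:**
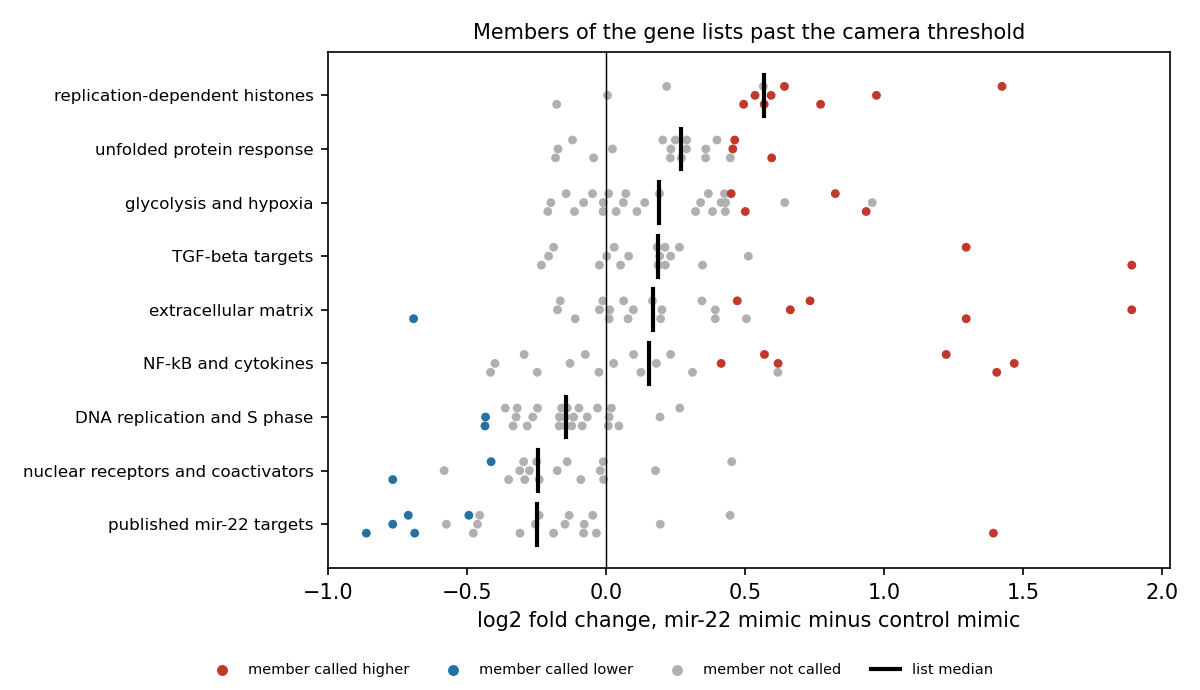
Log2 fold change, mir-22 mimic minus control mimic (x axis), of each measured member of the 9 gene lists past the camera threshold (y axis); red and blue points are members called higher and lower in limma, grey points are not called, and black bars are list medians. The medians run from -0.25 for published mir-22 targets to 0.57 for replication-dependent histones.

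Genes reported elsewhere as mir-22 targets, a list drawn from general knowledge and not from these samples, fell together (camera adjusted p = 0.00509, median log2 -0.25). With an estimated correlation the list's adjusted p was 0.355. That estimate, 0.00729, lay under the preset 0.01, so a higher correlation does not account for the loss. The list's raw camera p still rose from 0.000565 to 0.0242, so the rerun raises p-values for a reason besides correlation. Its adjusted p, here and for the lists below, is therefore not by itself a sign of correlated genes. Of its 22 measured members 5 were called lower and 1 higher, and adjusted over the list alone 11 were lower and 1 higher. The members lowered were MYCBP, a MYC-binding protein (-0.86 ± 0.13, adjusted p = 0.0109 in limma), the citrate lyase ACLY (-0.71), the transcription factor MECOM (-0.69), the receptor coactivator NCOA1 (-0.77) and the mitotic phosphatase CDC25C (-0.49). All 5 lost their calls when any 1 mimic array was left out, with MYCBP at -0.90, -0.88 and -0.80 without replicates 1, 2 and 3, and NCOA1 also lost its call without control mimic replicate 2 and CDC25C without control mimic replicate 1 or 2. CDK6, which the list also holds, rose by 1.39 ± 0.10 and was called whichever array was left out. The brightest probes of TP53INP1 (-0.08), SIRT1 (-0.08), ERBB3 (0.20) and HDAC4 (0.45) did not pass. With each array left out in turn HDAC4 ran from 0.232 to 0.638, and it passed in no alternative. SIRT1 was lower on every mimic array than on control mimic replicates 1 and 2, and without control mimic replicate 3 its log2 fold change was -0.43 and passed the threshold. The brightest probe of MAX was at -0.04, and of its other 3 probes one was called lower (-0.52, adjusted p = 0.0237) and the others were at -0.04 and -0.49. ESR1 was not kept by the detection filter, and MIR22HG had no probe named here.

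Replication-dependent histone genes rose as a group (camera adjusted p = 1.09e-06, median log2 0.57), and the adjusted p with an estimated correlation was 0.355. Of 12 measured members 8 were called higher and none lower, and 9 were higher adjusted over the list alone, among them H4C8 (1.43 ± 0.17), H2BC5 (0.97), H2AC18 (0.77) and H2BC9 (0.59). Calls of H4C8 and H2BC5 held without any 1 array, and those of H2AC18 and H2BC9 did not hold without mimic replicate 1, 2 or 3, nor that of H2AC18 without control mimic replicate 2. The other probe of H2BC5 was at 0.34 and not called. H4C3, the brightest measured member, was at -0.178 and not called. Copies of a histone class are near-identical, so the gene behind a probe is uncertain. Small nucleolar, small nuclear and other RNAs made without a poly(A) tail, a set chosen after the values were seen, moved the same way: the median over 51 such genes was 0.49, with 10 called higher and none lower. Their median lay 0.536, 0.47 and 0.396 above the mean of control mimic replicates 1 and 2 on mimic replicates 1, 2 and 3, and at -0.03 on control mimic replicate 3.

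Extracellular matrix genes rose (camera adjusted p = 0.00509, median log2 0.17), with 5 of 23 measured members called higher and 1 lower, and 8 and 1 adjusted over the list alone. The estimated-correlation adjusted p was 0.355. THBS1, the collagen gene COL1A1 (1.30 ± 0.13) and the fibrillin gene FBN1 (0.73) were higher, and the collagen gene COL12A1 (-0.69) was lower. TGF-beta targets rose too (adjusted p = 0.0127, median 0.19, 2 of 19 called higher and none lower, 3 over the list alone), with an adjusted p of 0.534 at an estimated correlation. Without control mimic replicate 3 its median was 0.108 (adjusted p = 0.00584). Its 2 called members, THBS1 and COL1A1, also belong to the matrix list, and its member SMAD7 (0.51) did not pass. Calls of THBS1 and COL1A1 held without any 1 array, and those of FBN1 and COL12A1 were lost without any 1 of the mimic arrays, and that of FBN1 also without control mimic replicate 2. Matrix proteases and their inhibitors had 4 of 17 members called higher and none lower, namely the urokinase gene PLAU (0.65), ADAM9 (0.58), ADAMTS1 (0.54) and TIMP3 (0.48), with 7 higher and 1 lower over the list alone, but the list did not pass (median 0.19, adjusted p = 0.068). It passed in 6 of 20 alternatives and in none that left out an array, where its median was 0.117 without mimic replicate 1, 0.304 without mimic replicate 3, and 0.323, 0.29 and 0.088 without control mimic replicates 1, 2 and 3. Of the 6 ways of leaving out 1 array, 4 ended the calls of PLAU and ADAMTS1 and 5 those of ADAM9 and TIMP3.

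Cytokine genes and other targets of NF-kB rose as a list (camera adjusted p = 0.0249, median log2 0.15), with 6 of 20 measured members called higher and none lower, and 7 higher and 3 lower adjusted over the list alone. The estimated-correlation adjusted p was 0.534. The interleukin genes IL11 (1.47 ± 0.13), IL1B (1.41 ± 0.16) and IL6 (1.22 ± 0.19) and the chemokine gene CXCL8 (0.57) were higher. Calls of IL11 and IL1B held without any 1 array, and those of IL6 and CXCL8 were lost without any 1 of the mimic arrays, and that of CXCL8 also without control mimic replicate 2. Without control mimic replicate 1 the list's adjusted p was 0.0681 and its median 0.09, and with the mean over a gene's probes the adjusted p was 0.0518. Its adjusted p ranged from 0.00584 to 0.534 over 20 alternatives. Immediate early genes did not pass (median 0.10, adjusted p = 0.111), although DUSP1 (0.72), FOS (0.76) and KLF2 (0.71) were called higher and FOSL1 (-0.91) lower (3 and 2 over the list alone). Interferon-induced genes did not pass either (median -0.04, adjusted p = 0.851), with IFIT2 (0.48) called higher and ISG20 (-0.79) and IFI35 (-0.64) lower among 22 measured (2 and 2 over the list alone). Leaving out 1 array ended the call of FOS in none of 6 cases, of DUSP1, FOSL1 and ISG20 in 2, and of KLF2, IFIT2 and IFI35 in 5.

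Chaperones and other genes of the unfolded protein response rose (camera adjusted p = 0.000717, median log2 0.27), with 3 of 19 measured members called higher and none lower, and 9 higher adjusted over the list alone. The estimated-correlation adjusted p was 0.534. The called members were SEL1L (0.60 ± 0.10), a factor that clears misfolded proteins, the stress transcription factor XBP1 (0.46) and the chaperone gene DNAJB11 (0.46). These calls were lost without any 1 of the mimic arrays and without control mimic replicate 1, and those of XBP1 and DNAJB11 also without control mimic replicate 2. The chaperone gene HSPA5 was at 0.45 with an adjusted p of 0.0527, and of 0.0456 with the replicate number as a block. Glycolytic and hypoxia-induced genes rose as well (adjusted p = 0.00109, median 0.19), with an estimated-correlation adjusted p of 0.534. Of 29 measured members 4 were called higher and none lower, and 7 higher over the list alone. They were the glucose transporter genes SLC2A3 (0.825 ± 0.10) and SLC2A1 (0.45), the peptide hormone gene ADM (0.94) and the collagen hydroxylase P4HA2 (0.50), of which the call of SLC2A3 alone held without any 1 array. Other probes of P4HA2 were at 0.54 and 0.11, the latter not called. Heat shock proteins had a median of 0.19 and 1 of 17 members called, HSPA1B (0.75), and missed the threshold at an adjusted p of 0.0527, which was 0.0349 with the replicate number as a block. The list passed in 9 of 20 alternatives, among them those without mimic replicate 1 (adjusted p = 0.0317) and without control mimic replicate 1 (0.0407) or 2 (0.0257), and without control mimic replicate 3 its median was 0.116 (0.125). The near-identical copy of HSPA1B, HSPA1A, was at 1.22 ± 0.43 and did not pass, and without control mimic replicate 3 it was at 0.62 and passed. The amino acid response list also missed the threshold (median 0.14, adjusted p = 0.0527, VLDLR called at 0.74 among 23), and passed it in 10 of 20 alternatives. Without control mimic replicate 3 its adjusted p was 0.00592, and without control mimic replicate 1 its median was 0.088 (0.191). Leaving out 1 array ended the call of HSPA1B in 1 of 6 cases and that of VLDLR in 2.

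DNA replication genes fell as a list (camera adjusted p = 0.0186, median log2 -0.15), with the clamp loader gene RFC3 (-0.44) and the polymerase gene POLA1 (-0.43) called lower among 27 measured members, also over the list alone, and none higher. The estimated-correlation adjusted p was 0.534. The other probe of POLA1 was at 0.06, and both calls were lost without any 1 array other than control mimic replicate 3 and with median scaling. Nuclear receptors and their coactivators fell as well (adjusted p = 0.0186, median -0.25), with NCOA1 (-0.77) and the retinoid receptor gene RXRB (-0.41) called lower among 18, and 5 lower and 1 higher over the list alone. The estimated-correlation adjusted p was 0.355, although the estimate for this list, -0.00249, lay under the preset 0.01. Without control mimic replicate 1 the adjusted p was 0.0599 for the replication list and for the receptor list, over ranges of 0.00353 to 0.534 and 0.00584 to 0.355 in their alternatives. With median scaling the adjusted p of the replication list was 0.052, and with the mean over a gene's probes that of the receptor list was 0.0518. Genes of mitotic entry and mitosis did not pass (median -0.06, adjusted p = 0.467, 1 of 28 called, CDC25C), except without control mimic replicate 3 (median -0.126, adjusted p = 0.0279), nor did deacetylases and repressors (median -0.08, adjusted p = 0.287), of which HDAC1 (-0.46) and EZH2 (-0.51) were called lower among 21. The calls of RXRB, HDAC1 and EZH2 were lost in 5 of the 6 cases of leaving out 1 array and with median scaling, and the other 2 probes of EZH2 (-0.34 and -0.31) were not called.

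Signalling lists had called members in both directions and did not pass camera. For PI3K, AKT and mTOR signalling (median -0.06, adjusted p = 0.731, 21 measured) FOXO3 (0.76) and PIK3R1 (0.42) were called higher and IRS1 (-0.75) and MLST8 (-0.55) lower, and with the replicate number as a block PIK3R1 had an adjusted p of 0.053. For RAS and MAPK feedback genes (median 0.02, adjusted p = 0.627, 19 measured) SPRY1 (0.75) was higher and FOSL1 lower. Among p53 targets (median 0.06, adjusted p = 0.253, 18 measured) MDM2 (0.58), TIGAR (0.57) and GADD45A (0.47) were higher and BAX (-0.48) lower (3 and 2 over the list alone). Among apoptosis regulators (median 0.05, adjusted p = 0.658, 20 measured) BID (0.76) and CFLAR (0.58) were higher and BAX lower (2 and 2 over the list alone). In the microRNA machinery (median 0.08, adjusted p = 0.499, 20 measured) the silencing scaffold TNRC6A (0.50) was higher and the decapping factor DCP1A (-0.84) lower (2 and 3 over the list alone). Of the 6 cases of leaving out 1 array, the call of SPRY1 was lost in 1, that of FOSL1 in 2, those of FOXO3, IRS1, BID and DCP1A in 3, those of MLST8 and MDM2 in 4, and those of PIK3R1, TIGAR, GADD45A, BAX, CFLAR and TNRC6A in 5. Other probes of BAX (-0.24), PIK3R1 (0.14) and TNRC6A (-0.05 and 0.38) were not called, and that of BID (0.46) was. The other named genes whose call changed with the replicate number as a block were DICER1 (0.44, adjusted p = 0.0487), CNOT1 (-0.43, 0.0407), RIGI (0.44, 0.037), CDH2 (0.65, 0.0391), SMAD7 (0.51, 0.0336), RARA (-0.58, 0.0224) and RXRA (0.45, 0.0425), which passed with the block and not without it. Other probes were at 0.26 for CNOT1 and -0.18 for RARA, neither called without the block.

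Lipid and organelle lists did not pass. Fatty acid synthesis had a median of -0.01 (adjusted p = 0.947, 18 measured), with ACLY (-0.71) and ACACA (-0.53) lower and GPAM (0.69) higher. Lysosome and autophagy genes had a median of -0.07 (0.455, 26 measured), with NPC2 (-0.69), WIPI1 (-0.67) and ULK1 (-0.52) lower, and ribosome biogenesis genes one of 0.01 (0.936, 24 measured), with NOLC1 (-0.69) lower. No member was called for cholesterol synthesis (median 0.12, adjusted p = 0.466), oxidative phosphorylation (-0.06, 0.499), ribosomal proteins (0.01, 0.658), the proteasome (0.00, 0.936) or integrins and focal adhesion (0.08, 0.27), the last with 7 higher and 2 lower adjusted over the list alone. Among actin regulators (median -0.06, adjusted p = 0.629) RHOB (1.05) was called higher among 28 measured. Leaving out 1 array ended the call of NOLC1 in 2 of 6 cases, of ACLY, NPC2 and RHOB in 3, of ACACA and ULK1 in 4, and of GPAM and WIPI1 in 5. The other probe of ACACA (-0.33) was not called. For fatty acid synthesis (mean 0.02) and the proteasome (mean 0.01) the mean and camera's direction were upward and the median was below 0, and for ribosome biogenesis the mean was -0.003 while the median and camera's direction were upward.

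Marker lists of cell types did not pass camera in limma. Few leukocyte and endothelial markers were measured, 5 and 7, and none was called (medians -0.12 and -0.04, adjusted p = 0.466 and 0.936). Of 6 fibroblast and smooth muscle markers COL1A1 was called higher and ACTA2 (-0.77) lower (median 0.02, adjusted p = 0.658). Epithelial genes had no called member among 9 (median 0.08, adjusted p = 0.658), mesenchymal genes had SNAI2 (0.44) called higher and FOSL1 and ACTA2 lower among 20 (3 and 2 over the list alone, median -0.08, adjusted p = 0.858), and clear cell carcinoma markers had IL6 called higher among 14 (median 0.06, adjusted p = 0.48). Leaving out 1 array ended the call of ACTA2 in 2 of 6 cases and that of SNAI2 in 5. In lists without a count over the list alone here, that count equalled the one over all probes.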

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

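Leaving out both number 3 arrays was chosen after the data were seen, and all other alternatives were planned. The direction of the 1210 called probes held in each alternative that tested them. Groups of arrays did not overlap for any of these probes, which left little room for a change of sign. Between 7 and 13 lists passed under every alternative except 2 of the list tests. The replicate number as a block gave 1577 probes (752 at 1.5-fold) and 1233 genes, and changed no call of a named gene or list other than those given with the results. Causes of the changes below were not tested. Fewer arrays or a spread estimated from a single probe leave less to test with. The number of arrays alone does not account for the counts, since leaving out control mimic replicate 3 raised the called probes from 1210 to 2639. Deviations from the group mean had an SD of 0.2875 on that array and of 0.0985 to 0.1699 on the others. Array weights, which gave control mimic replicate 3 a weight of 0.143, called 4405 probes (2188 higher, 2217 lower) and 3277 genes (1626 and 1667). A gene with probes called in both directions counts in both, here and below. The per-probe test without shared variance called 325 probes (171 higher, 154 lower), 189 at 1.5-fold (100 and 89), and 270 genes (147 and 123). Without both number 3 arrays there were 2882 probes (1499 and 1383) and 2199 genes (1148 and 1056), 1208 of the probes among the 1210. Over the arrays left out in turn, probes ran from 133 to 2639 (74 to 1416 higher, 58 to 1223 lower), those at 1.5-fold from 133 to 691 (74 to 396 and 58 to 301), genes from 104 to 2023 (61 to 1087 and 42 to 940), and lists from 7 to 11. At 1.5-fold, 430 probes (224 lower) passed with no background correction and 335 (159 higher, 176 lower) with an offset of 50, which compresses folds. Of the 9 lists, 0 passed camera with an estimated correlation, where raw p-values lay from 0.0136 to 0.166, and 14 lists passed fry, including all 9. Estimates ran from -0.00249 (nuclear receptors) to 0.209 (unfolded protein response). For nuclear receptors and published mir-22 targets (0.00729) they lay under the preset 0.01, so there a higher correlation does not account for the loss. Their raw camera p-values still rose, from 0.00412 to 0.0361 and from 0.000565 to 0.0242. A list lost in that rerun is therefore not by itself a sign of correlated genes. Over alternatives the calls of named genes were lost 302 times (169 of higher genes, 133 of lower) and gained 124 times (66 and 58), and those of lists 15 times (8 and 7) and 31 times (28 and 3). Apart from arrays left out, 14 named calls were lost with median scaling (RFC3, POLA1, MDM2, BAX, MLST8, PIK3R1, DNAJB11, ACACA, SLC2A1, ULK1, SNAI2, HDAC1, EZH2 and RXRB), 13 without a detection filter (TNRC6A, BAX, CFLAR, MLST8, KLF2, IFI35, GPAM, WIPI1, ULK1, FBN1, ADAM9, EZH2 and NCOA1), that of GPAM with cyclic loess and that of PIK3R1 with a trended and robust variance. The per-probe test lost 51 of the 84 and kept those of IL1RL1, THBS1, ANXA10, H4C14, IL11, CDK6, GSTM3, BNC2, SFXN2, EEF2K, DPM2, TTLL5, PRELID1, ITGA10, LEF1, LYPLA2, CLCC1, H2BC9, MDM2, BID, SPRY1, FOS, DUSP1, ISG20, CXCL8, XBP1, VLDLR, HSPA1B, SLC2A3, NOLC1, COL1A1, PLAU and ACTA2. Of lists, the calls of DNA replication genes (median scaling) and of the cytokine and nuclear receptor lists (mean over a gene's probes) were lost. The 31 calls gained were of the amino acid response (10), heat shock proteins (9), matrix proteases (6), immediate early genes (2, without a filter and in fry), mitotic genes (1, without control mimic replicate 3), and integrins, mesenchymal genes and oxidative phosphorylation (1 each, in fry). The amino acid response and matrix proteases passed with either other background correction, median scaling, no filter and a trended and robust variance, the first also with cyclic loess, detection on all 6 arrays, array weights, without control mimic replicate 3 and without both number 3 arrays, and the second also in fry. Heat shock proteins passed with either other background correction, median scaling, no filter, the block, a trended and robust variance, and without mimic replicate 1 or control mimic replicate 1 or 2.

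No called gene or list changed sign, though for genes this says little, since the groups of arrays did not overlap for any called probe. Some values near 0 that were not called did change sign, and the ranges here are over the arrays left out in turn. MAX was at 0.032 with cyclic loess, 0.039 with array weights, 0.073 without both number 3 arrays and in a range of -0.121 to 0.075. TP53INP1 was at 0.03 without both number 3 arrays and in a range of -0.195 to 0.027, and SIRT1 in a range of -0.425 to 0.118. List medians changed sign for the proteasome (0.000 without background correction, 0.001 with an offset of 50, 0.022 with median scaling, 0.041 with cyclic loess, range -0.036 to 0.01), fatty acid synthesis (0.007 with median scaling, 0.034 with cyclic loess, 0.017 with array weights, 0.01 without both number 3 arrays, range -0.035 to 0.049) and ribosomal proteins (-0.037 in the authors' value table, -0.026 with array weights, -0.011 without both number 3 arrays, range -0.016 to 0.006). They also did for ribosome biogenesis (-0.003 in the authors' value table, range -0.024 to 0.018), interferon-induced genes (0.01 with cyclic loess), endothelial markers (0.02 without a filter, range -0.16 to 0.078) and, without both number 3 arrays, RAS and MAPK feedback (-0.003, range -0.023 to 0.046), actin regulators (0.003, range -0.103 to 0.026) and clear cell markers (-0.002, range -0.016 to 0.206). The range crossed 0 for fibroblast markers (-0.056 to 0.151), epithelial genes (-0.011 to 0.092) and mesenchymal genes (-0.099 to 0.015). Without a change of sign, medians of lists that did not pass ran from 0.002 to 0.082 for apoptosis regulators, 0.034 to 0.137 for cholesterol synthesis, -0.146 to -0.06 for deacetylases and repressors, -0.126 to -0.006 for mitotic genes, 0.048 to 0.15 for immediate early genes, 0.017 to 0.109 for integrins, -0.082 to -0.009 for interferon-induced genes, -0.157 to -0.073 for leukocyte markers, -0.126 to -0.015 for lysosome and autophagy, 0.027 to 0.131 for the microRNA machinery, 0.023 to 0.136 for p53 targets and -0.119 to -0.008 for PI3K, AKT and mTOR signalling. Seed matches and slides were not run, and the per-probe test gives no list value. Signal over background limits which genes could be compared: 18732 of the 48803 probes were kept, and ESR1 was not among them.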

Other observations

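Genes with several kept probes that were all called in limma, a set chosen after the values were seen, numbered 73, with 38 higher and 35 lower with the mir-22 mimic. The 3 probes of PLOD2, a lysyl hydroxylase of collagen, were higher by a mean log2 of 1.20 (0.823 to 1.597), and the 3 of the transcription factor gene STAT3 by 0.73. The secreted proteins FAM3C (1.04) and IL24 (0.99, probes at 0.648 and 1.325), the receptor kinase gene KIT (0.58) and the gene of its ligand, KITLG (0.67, probes at 0.468 and 0.864), were higher by both of their probes. On the lower side stood RFXANK, a regulator of class II antigen presentation (3 probes, mean -1.07), NHP2, a protein of small nucleolar ribonucleoproteins (-1.06), the ubiquitin ligase gene CBL (-0.95) and GEMIN2, which takes part in assembling small nuclear ribonucleoproteins (-0.82). Adjusted p-values of the probes of the 73 genes were at most 0.0477 (limma).

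Of 39 histone genes measured, also a set chosen after the values were seen, 16 were called higher and 1, H2AJ (-0.58), lower. Of the 6 genes of histone H4 measured 5 were higher, with log2 control means of 5.04 to 5.93. The other, H4C3, was far brighter (13.76 in controls, 13.58 with the mimic) and was not called (-0.178). H2AJ is a histone variant gene, and the variant genes H2AZ1 (0.03), H2AZ2 (-0.17), H1-10 (-0.02) and H2AX (-0.61) did not pass. Of the RNAs made without a poly(A) tail, SNORD16 (1.17 ± 0.09), SNORD36C (0.99) and SNORD68 (0.97) were the highest of those called, while the signal recognition particle RNA gene RN7SL1 was at 0.03 and SNORD109B at -0.22, neither called.

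In the weighing that follows, the tests of a swapped array, of RNAs without a poly(A) tail and of S phase genes were chosen after the values were seen, and the comparison of probes within genes and the count of splits were set before their results. Control mimic replicate 3 stood apart through probes that lost signal: 684 of its probes lay over 1 log2 unit below the other controls, against 16 such probes on mimic replicate 3 against the other mimics. If transcripts differed in that culture, 2 probes of a gene should deviate together. Over 2915 genes the correlation between 2 probes of a gene was 0.232 for this array's deviation and 0.713 for the mimic's effect against controls 1 and 2, a difference of -0.481 (bootstrap interval -0.527 to -0.429, across genes, which are not independent replicates). The same correlation was 0.112 for the deviation of mimic replicate 3 from the other mimics and 0.078 for control 1 minus control 2, both under 0.232, so part of this array's deviation may be shared by the probes of a gene. Mimic replicate 3 shared the low raw intensity and high bead error of control mimic replicate 3. It is therefore not a clean comparator, and an effect common to both number 3 arrays stays open. A swap with a mimic array is argued against. Over probes called without it, control mimic replicate 3 lay 0.065 of the way from controls 1 and 2 to the mimics. The interval was 0.037 to 0.096, across probes, which are not independent replicates. On principal component 2, however, control mimic replicate 3 lay at 8.65, within the range of the mimic arrays (6.61 to 18.09). A fault of hybridisation or labelling that acts on single probes may account for part of the deviation, while RNA quality or a real difference in part of the transcripts stays open, and no biological explanation was tested because the design names none within a group.

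The rise of replication-dependent histone genes may come from more RNA without a poly(A) tail being labelled on the mimic arrays, which such a cause predicts for small nucleolar and nuclear RNAs as well. Over 51 of these genes the median log2 change was 0.486, above 0.284, which is 0.5 of the histone median. Its bootstrap interval was 0.432 to 0.608, across genes, which are not independent replicates. The median stayed between 0.452 and 0.534 with any 1 array left out on the same normalised values. Not every RNA of the 2 sets rose: the brightest histone member, H4C3, was at -0.178 and RN7SL1 at 0.026, neither called. A larger share of cells in S phase is argued against, since replication genes had a median of -0.146 (interval -0.247 to -0.086, across genes, which are not independent replicates). That list's call was lost at an estimated correlation (adjusted p = 0.534), with median scaling (0.052) and without control mimic replicate 1 (0.0599), while its median stayed between -0.195 and -0.108 over 20 alternatives, so a small rise in the share of such cells is not ruled out by the list's test. Whether these RNAs were more abundant in the mimic cells, through mir-22 or otherwise, or were only labelled more efficiently stays open, because both would move the 2 sets alike.

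The count of called probes was set against other ways of dividing the 6 arrays. There are 10 splits into 3 and 3, and 1 of them, the real one, gave as many as 1210 probes in limma, while the highest of the others gave 0, with 94 to 963 probes at an unadjusted p under 0.05 against 4336. Of the other splits, 3 part all 3 pairs of equal number, and these also gave 0. With 10 splits a share under 0.05 cannot be reached.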
